A study of Streptococcus thermophilus with 3 samples.

How the data were processed

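Total RNA of *Streptococcus thermophilus* LMD-9 and of its hdiR knockout CB0082 was compared on 3 custom two-colour arrays. Per the labels' protocols, cells from a 16 h preculture were washed, diluted 30-fold in chemically defined medium with 1% lactose and grown at 37°C, and 25 ml were collected at an optical density of 0.4. Per the labels' protocols, cDNA made from 10 microg of RNA was labelled indirectly with Alexa Fluor 555 (green) or Alexa Fluor 647 (red). On array 1 the knockout was red, and on arrays 2 and 3 it was green. All ratios were turned to knockout over wild type from these dye labels.

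Spots were quantified with Agilent Feature Extraction 9.1, per the submitters' processing notes, in version 9.1.3.1 per the file headers. The deposited intensity values were mean and median pixel signals and local background medians of each spot, with no background correction. The deposited processed intensity values had a spatial trend removed and were dye normalised with lowess at a smoothing factor of 0.25, per the file headers. The deposited log10 ratio is red over green of these processed signals. The authors' value table was identical to this log10 ratio in all 15744 rows of each array, with medians of -0.00479, -0.00159 and -0.0064, so its scale and direction are known and it was not turned for the dye swap. No genome build is given in the sources used here.

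Mean signals were corrected with the background medians by normexp with an offset of 50 and normalised by loess within each array, with control spots at weight 0 (R 4.3.3, limma 3.58.1). Of the 15744 spots per array, 15208 belonged to loci. Non-uniform and population outlier spots were left out, which concerned 175 spot values over the 3 arrays, and no spot was saturated. Spots were averaged per probe (6798 probes had 2 spots and 1612 had 1). A probe was kept when it was well above background on all 3 arrays in the channel of at least 1 strain, and 38 probes were left out, 15 of them for this reason. The value of a gene was the mean of its kept probes, and 2 loci had none. The share of spots well above background was 99.75% to 100% over arrays and strains, and the number of arrays limits the precision.

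Arrays 1 and 3 share their RNA extracts and were averaged to 1 value. This value and array 2 entered a limma intercept fit with empirical Bayes moderation (prior degrees of freedom 9.66) and Benjamini-Hochberg adjustment at 0.05. A second count added an absolute log2 ratio of at least 1. The labels describe the 2 clones as biological replicates. The design, the rule for named genes, 18 gene lists and the alternatives were fixed before the data were examined. The rule named hdiR and its neighbours, then the 12 largest increases and the 12 largest decreases that passed with the same sign on all 3 arrays, then members of the lists. Because the files do not pair locus tags with names, 0 of the 18 lists had a matched member, and the planned hdiR value and gene list tests were not run. For the same reason only the first 2 tags of each direction are named.

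The fit was tested on simulated data for 1921 genes with 200 changed. It called 3 of 50 genes at an absolute log2 ratio of 0.5, 48 of 50 at 1, and 50 of 50 at 2 and at 3, with 4 calls among 1721 unchanged genes and no wrong sign. The simulated errors were independent between the 2 clone values and equal on arrays 1 and 3. An error shared by arrays 2 and 3 through slide, scan or dye was not simulated, so these rates do not cover it. Alternatives covered the background correction, the signal column, the normalisation, the filters, the probe summary, a dye or slide term, the treatment of replicates, the variance prior, the authors' value table and leaving out each array. One alternative, no filter on dim probes with flagged spots kept, was chosen after seeing the data. Tests by tag prefix, the search for consecutive tags and the translation of probes were also chosen after seeing the data.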

Results

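Gene expression of *Streptococcus thermophilus*, a lactic acid bacterium used in milk fermentation, was compared between the wild-type strain LMD-9 and strain CB0082, in which hdiR is knocked out. HdiR is known from the related *Lactococcus lactis* as a LexA-type repressor that is cleaved after DNA damage. Both strains were sampled in mid-log growth at 37°C, at an OD600 of 0.4, in a chemically defined medium with 1% lactose. The data were 3 two-colour arrays, and each array carried wild-type and knockout cDNA in opposite channels. Arrays 1 and 3 held the same 2 RNA extracts, from clone 1 of each strain, with the dyes swapped, and array 2 held clone 2, so the comparison rested on 2 biological replicates. The 2 values were not technically independent, since arrays 2 and 3 shared slide, scan and dye orientation. The p-values of the main fit do not cover an error shared in this way. A dye effect cancels in the mean of arrays 1 and 3 but not on array 2, so part of it stays in the log2 ratios. The arrays carried 8410 probes for 1923 locus tags, of which 1921 could be tested with a median of 5 probes each. The median knockout signal was 6690, 4819 and 4879 on arrays 1, 2 and 3, and the median wild-type signal was 5753, 3104 and 3794, against 54.8 to 63.9 for the negative control spots. The number of arrays, 3, limits the precision. The files gave loci by tag only, with no gene names, products or positions, so hdiR itself could not be looked up by name and at most 2 tags that rose and 2 that fell are named.

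The first question was which genes changed when hdiR was lost. In the knockout, 20 genes rose and 21 fell among the 1921 tested (limma, Benjamini-Hochberg adjusted p below 0.05), and 227 had an unadjusted p below 0.05. The genes that rose did so by 1.64-fold to 7.69-fold, with a median of 3.21-fold. Of these, 19 were higher on all 3 arrays and 12 were at least 2-fold higher on every array. All 81 probes of the 20 genes had a mean ratio above 0. The genes that fell had smaller ratios, from -1.72 to -0.63 on the log2 scale, and 18 of the 21 were lower on all 3 arrays. When a term for dye, slide or scan was fitted, this term passed for 10 of the 21 (limma, adjusted p below 0.05). It passed for 403 of all 1921 genes. All 21 stayed called lower in that fit, which takes its spread from arrays 2 and 3 alone. By contrast, 0 genes were called lower with the 3 arrays taken as independent. Of all genes tested, 99.12% differed by less than 2-fold. The total depended on single arrays: it was 431 (180 higher, 251 lower) without array 1 and 19 (15 higher, 4 lower) without array 3. Without array 1, both remaining arrays shared slide, scan and dye orientation. A dye or slide error then cannot be told apart from a change in the knockout. With each array centred on its median in place of loess, 89 genes passed, of which 26 were higher and 63 lower.

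At a change of at least 2-fold, 15 genes passed, 13 higher and 2 lower in the knockout. Without array 1 there were 26, of which 14 were higher and 12 lower. STER_0543 rose most, 7.69-fold (log2 2.94 ± 0.66, SD, n = 2 clones; SE 0.197, limma adjusted p = 5.412e-06). Its ratio was 4.02 on array 1, 2.48 on array 2 and 2.80 on array 3 on the log2 scale, and all 5 of its probes were higher. The lowest of the 5 read 2.745, 1.769 and 1.969 on the 3 arrays, and the probe means of STER_0543 had an SD of 0.57. Its probe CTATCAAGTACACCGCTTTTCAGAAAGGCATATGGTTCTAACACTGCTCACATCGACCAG read 4.46, 2.74 and 3.15 on the 3 arrays. STER_0921 rose 4.72-fold (log2 2.24 ± 0.14, SD, n = 2 clones; SE 0.139, limma adjusted p = 5.048e-06), with nearly equal ratios of 2.18, 2.34 and 2.09 on the 3 arrays. Its probe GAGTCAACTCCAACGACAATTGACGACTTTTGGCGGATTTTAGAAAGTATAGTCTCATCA read 2.17, 2.30 and 2.12 on the 3 arrays. The other 11 genes that rose at least 2-fold lay between 2.19-fold and 4.66-fold. All 13 were called higher in 16 of the 17 other settings tested, and 12 of them when the 3 arrays were taken as independent. Not all of the 17 are separate: a quantile step after loess moves no ratio, and the authors' value table repeats the processed signals.

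**Figure D1:**
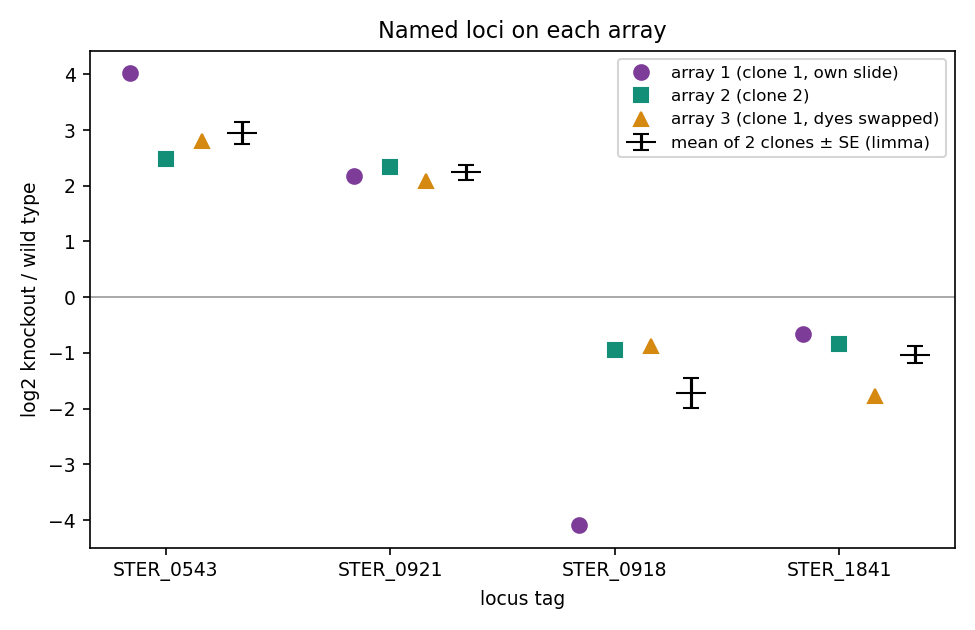
Log2 ratio of knockout over wild type (vertical axis) of the 4 named loci (horizontal axis) on each of the 3 arrays, with the mean of the 2 clones and its limma standard error as bars. The standard error is moderated toward the spread of all genes, so it does not show the spread of the 2 clones of a locus. STER_0921 has nearly equal values on the 3 arrays, while STER_0543 and STER_0918 lie much farther from 0 on array 1, at 4.02 and -4.09, than on arrays 2 and 3.

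The genes that rose stood side by side. Of the 20, 16 lay in 6 runs of 2 to 4 consecutive locus tags and 4 stood alone. STER_0921 closed a run of 3 tags whose log2 ratios of 2.06, 2.21 and 2.24 differed by little more than their standard errors of 0.135 to 0.139. A second run of 3 tags had log2 ratios between 1.65 and 2.22. A pair of neighbouring tags lay at 1.98 and 2.14, and another pair at 1.72 and 1.93. The run of 4 tags and the last pair rose less, by 0.72 to 0.91 and by 0.77 on the log2 scale, and the run of 4 lay between -0.07 and 0.68 on array 1. With the 3 arrays taken as independent, 0 of these 6 genes were called, and without array 3, 1 was.

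The tag directly before the run of STER_0921 was that of STER_0918, the locus with the lowest mean over the clones. This rank rests on array 1: without it, the log2 ratio was -0.91, and several called loci lay lower, among them STER_1841 at -1.31. STER_0918 was then not among the 12 loci lower at least 2-fold. STER_0918 had a log2 ratio of -1.72 ± 1.08 (SD, n = 2 clones; SE 0.270, limma adjusted p = 0.006987). On array 1 its log2 ratio was -4.09, and on arrays 2 and 3 it was -0.95 and -0.87. The knockout signal was 120 on array 1, where 6 of its 8 spots were well above background, against 1635 for the wild type. On arrays 2 and 3 the knockout signals were 619 and 646 against 1033 and 1256 for the wild type. The 3 probes with every knockout spot well above background on array 1 had log2 ratios of -4.20 to -3.31 there, with a mean of -3.89. Of the other 2, 1 had no such spot, so the -4.09 includes values that are not well measured. On arrays 2 and 3 all 5 probes lay between -1.06 and -0.80. Its direction held in all 18 other settings, but its call was lost with the 3 arrays taken as independent (adjusted p = 0.3768) and with a trended and robust prior (adjusted p = 0.5814).

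**Figure D2:**
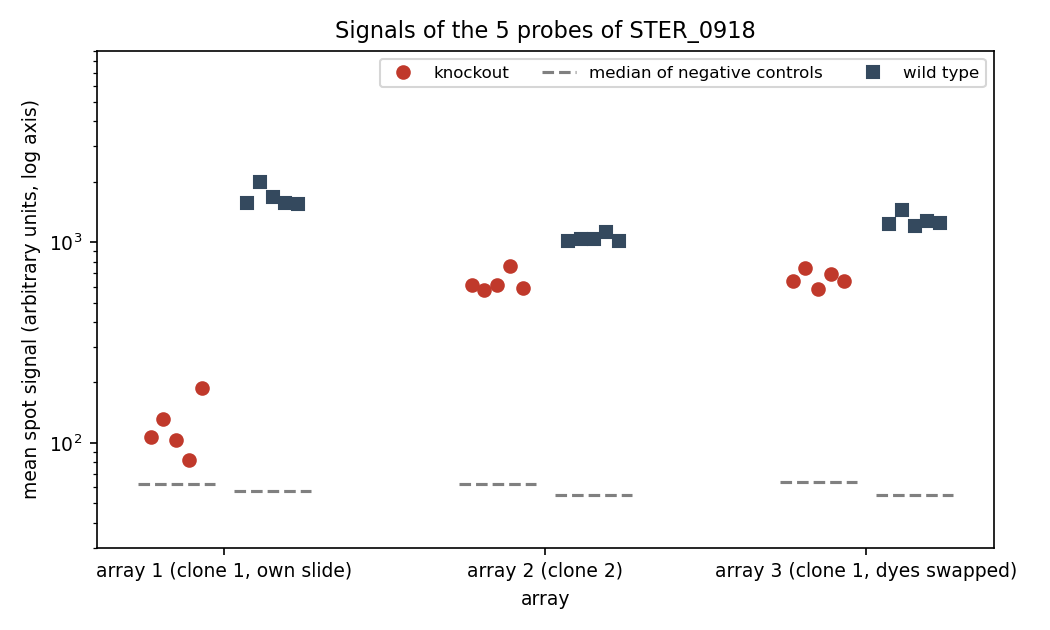
Mean spot signal in arbitrary units (vertical log axis) of the 5 probes of STER_0918 in the knockout (circles) and the wild type (squares) on each array, with the median of the negative controls as dashed lines. Knockout probes lie between 81.8 (not well above background) and 187 on array 1 and between 580 and 763 on arrays 2 and 3.

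The other locus that fell at least 2-fold was STER_1841, with a log2 ratio of -1.03 ± 0.26 (SD, n = 2 clones; SE 0.147, limma adjusted p = 0.003394). Its log2 ratio was -0.66, -0.85 and -1.77 on arrays 1, 2 and 3, so it was lower in 3 of 3 arrays. The call was lost without array 3 (log2 -0.75, adjusted p = 0.1142) and with the 3 arrays taken as independent (adjusted p = 0.19). STER_1841 stood in a run of 7 consecutive tags that all fell, by log2 ratios of -1.03 to -0.76, and all 7 were lower on every array. None of the 7 was called without array 3 (adjusted p from 0.1142 to 0.4904) or with the 3 arrays taken as independent (adjusted p = 0.19). Their log2 ratios were -0.75 to -0.59 in the first of these settings and -1.09 to -0.81 in the second. A further run of 3 tags fell, with log2 ratios of -0.85 to -0.71, and 0 of its 3 calls were kept in either of these settings. Of the 21 genes that fell, 6 carried a tag with the prefix r, which 8 of the tested loci have. The 8 loci with this prefix had a median log2 ratio of 0.33 on array 1 but of -0.97 and -1.58 on arrays 2 and 3. With median centring in place of loess, the split was wider, at 1.84, -2.09 and -2.49.

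The dye swap made it possible to ask how far the arrays agreed. Across the 1921 genes, which are not independent replicates, log2 ratios of arrays 1 and 3, which held the same RNA, had a Pearson correlation of 0.324 and a Spearman correlation of 0.18. Arrays 2 and 3, which held different clones on the same slide in the same dye orientation, had correlations of 0.745 and 0.636. Arrays 1 and 2 had correlations of 0.085 and -0.225. The SD of the difference between arrays was 0.458 for arrays 1 and 3, 0.251 for arrays 2 and 3 and 0.506 for arrays 1 and 2. Without the 41 called genes the Pearson correlations were 0.119, 0.643 and -0.261. With median centring they were 0.14, 0.85 and -0.07 over all genes. Array 1 alone had its slide, its scan and its dye orientation, so these 3 factors could not be told apart. With a term for them, 368 genes passed (157 higher, 211 lower), among them all 41 of the main comparison; this fit takes its spread from arrays 2 and 3 alone, on the same slide.

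**Figure D3:**
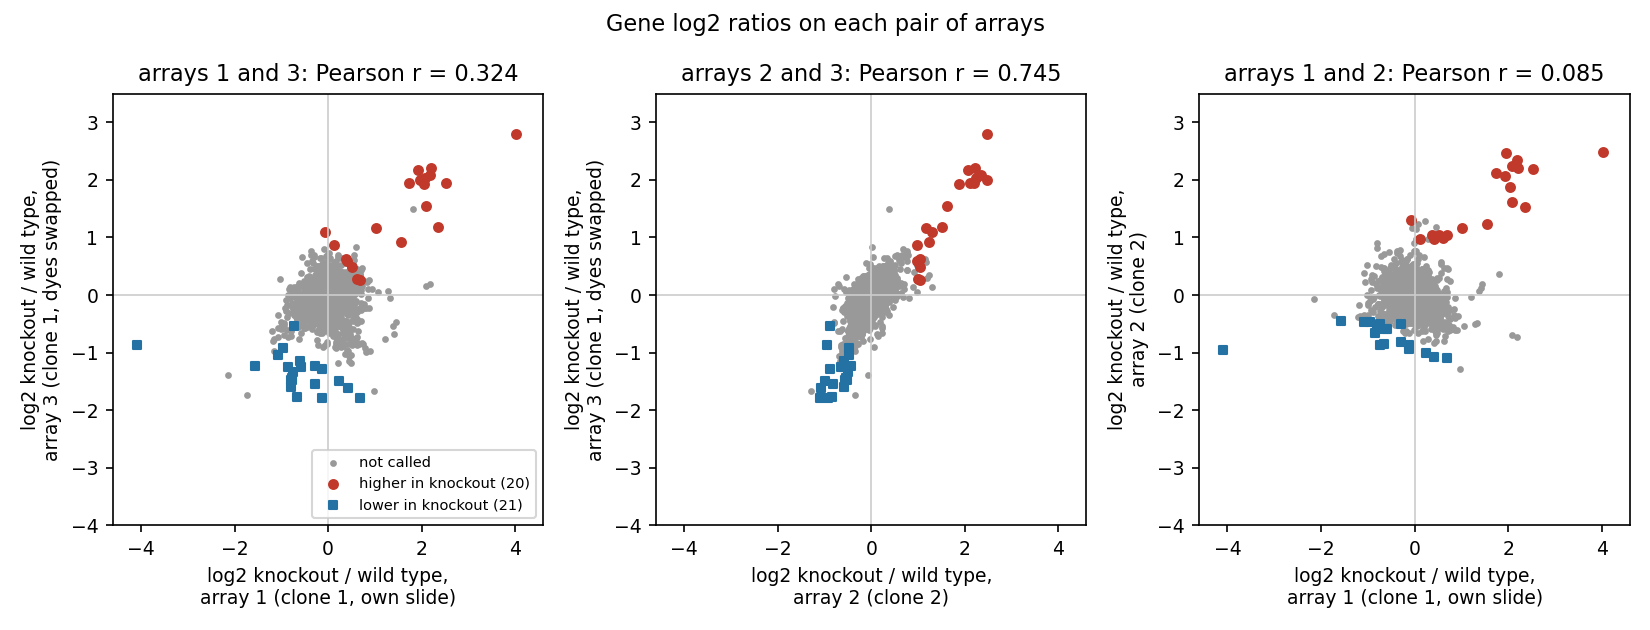
Log2 ratio of knockout over wild type of each of 1921 genes on 1 array (horizontal axis) against another (vertical axis), for the 3 pairs of arrays, with 20 genes called higher as red circles, 21 called lower as blue squares and the rest in grey. The red genes lie at the upper right for each pair, except for 1 red gene at -0.07 on array 1, and over the genes not called the Pearson correlation is 0.119 for arrays 1 and 3, 0.643 for arrays 2 and 3 and -0.261 for arrays 1 and 2.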

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

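The tests in this part were chosen after the results were seen. The fit with a dye or slide term and the other scalings were planned, but their use on the groups and loci below was not. No outlier test applies, since there are 3 arrays.

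The 13 genes at least 2-fold higher in the knockout were higher on all 3 arrays. A dye, slide or scan effect would turn or vanish on array 1, but the lowest of the 13 had a log2 ratio of 1.02 there, against an SD of 0.42 over all genes of that array. Cross-hybridisation of single probes would leave other probes of a gene near 0, but in 12 of the 12 genes with over 1 probe, most probes read at least 0.8, and the lowest of all 60 probes read 0.67. The gene with 1 probe stays open in this respect. Loss of hdiR is a candidate explanation that stays untested, since no strain with hdiR restored was analysed here, and a second change in CB0082 remains open too.

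Ratios of 403 genes differed between array 1 and arrays 2 and 3 in a fit with a term for dye orientation, slide or scan (limma, adjusted p below 0.05), and 264 of them had opposite signs on the 2 sides. This fit sets a single array against 2 and takes its spread only from arrays 2 and 3, on the same slide in the same orientation, so the count leaves out the spread between slides. The loci with prefix r or t on their tag are among the groups that split this way. The 8 r-tagged loci had a median log2 ratio of 0.33 on array 1 and of -0.97 and -1.58 on arrays 2 and 3, and the 33 t-tagged loci of 0.45, -0.41 and -0.71. These signs were the same under median centring and 3 other scalings. The sizes were not: with median centring the medians of the r-tagged loci were 1.84, -2.09 and -2.49. Of the 8, 0 were then lower on all 3 arrays, against 3 in the main setting. In the fit with the term, the median of the t-tagged loci was -0.03, so their lower clone mean is consistent with a dye, slide or scan effect. The median of the r-tagged loci was still -0.48, with 6 of the 6 called loci still lower, so such an effect cannot be told apart from a lower level for them: a dye effect alone would cancel there, while array 1 is the only array of its slide and scan. This fit was run on the loess values only. Before normalisation, the 6 called loci were brighter in red than in green on every array. Camera with a preset correlation called both groups lower (adjusted p = 2.784e-12 for r and 1.408e-08 for t), and neither call held with an estimated correlation (adjusted p = 0.2553 and 0.4641). The third group tested, 4 loci with prefix A, was called higher with the preset correlation (adjusted p = 0.02759; 0.4641 with an estimated one), with medians of 1.40, 0.10 and -0.61 on arrays 1, 2 and 3. A bias of the brightest spots cannot be told apart for the r-tagged loci, since 6 of the 8 were brighter than every plain-tagged locus. An array 3 that held clone 2 would give the same split, so it is open as well.

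STER_0918 had a term of -1.59 for dye, slide or scan, in the same fit, from log2 ratios of -4.09 on array 1 and of -0.95 and -0.87 on arrays 2 and 3. A different level in the 2 clones would set array 3 beside array 1, but array 3 differed from array 1, of the same RNA by the labels, by 3.22 and from array 2 by 0.08. A raised level of dim spots on the slide of arrays 2 and 3 was seen, but was too small in most loci: 40 loci as dim on array 1 rose from a median knockout signal of 132 to 226 and 217, and 2.5% of them reached the knockout signal of STER_0918 on both arrays. Wild-type cDNA in the knockout channel of arrays 2 and 3 would need a share of 50.2%, with array 1 taken as unmixed, and would shrink the 13 raised genes to a median log2 ratio of 1.38, but they lay above that prediction by a median of 0.56, 11 of 13 of them above it. Binding of other cDNA to these probes on that slide, and a mislabelled array, were not tested.

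A control probe outside the comparisons read between 1540 and 4640 in both channels of the 3 arrays, above the 54.8 to 63.9 of the negative controls. It read 1830 (knockout) and 1540 (wild type) on array 1, 4280 and 4330 on array 2, and 4640 and 4590 on array 3. Why it was brighter in both channels on the slide of arrays 2 and 3 was not tested.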

How the results depend on the processing

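The count of changed genes, 41 in the main comparison, lay between 30 and 60 under 9 alternatives. It was 89 with median centring, 26 with flagged spots kept, 368 with a dye or slide term, 12 (all higher) with 3 arrays taken as independent and 104 with a trended and robust prior. It was 19 with no filter on dim probes and flagged spots kept, an alternative chosen after seeing the data. Leaving out an array gave 19 to 431. The prior degrees of freedom were 9.66 in the main fit and 7.57 with flagged spots kept. They were 6.86 with no filter on dim probes and flagged spots kept. Whether this or another cause moved the counts was not tested. The count at 2-fold or more, 15 in the main comparison, was 28 with median centring (13 higher, 15 lower) and 18 to 26 without an array (14 higher and 12 lower without array 1), and otherwise 12 to 18. Of the 13 genes raised at least 2-fold, 13 were called higher in 16 of 17 settings and 12 in the other. The correlation moved with median centring to 0.14 for arrays 1 and 3 and 0.85 for arrays 2 and 3, and turned to -0.07 for arrays 1 and 2; the cause was not tested. The 4 named loci kept their direction in 18 settings each, with ranges of 2.64 to 3.41 for STER_0543, 2.14 to 2.38 for STER_0921, -2.52 to -0.91 for STER_0918 and -1.31 to -0.75 for STER_1841. The quantile step after loess moves no ratio by construction, so its equal counts say nothing. The authors' value table holds the same ratio as the processed signals, so these are not separate settings. The clone as a random block could not be fitted, since its correlation could be estimated for 0 genes. Leaving out array 2 left 1 pair of extracts and gave values only. The hdiR value and the gene list tests were not run under any setting. No separate paired fit was run, because every array holds both strains and the pairing is already part of each ratio. Signal over background limits few genes: 1923 in place of 1921 were tested with no filter on dim probes.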

Other observations

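All tests in this part were chosen after the results were seen.

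Of the 13 genes raised at least 2-fold, 10 had another of the 13 at a neighbouring tag number, while 10000 random sets of 13 plain-tagged loci gave a mean of 0.16 and a maximum of 4 (one-sided permutation p = 0.0001, the smallest these sets can give). This argues against a random placement among the tags; why the genes stand together was not tested. Among the genes that fell, 10 of 21 lay in runs of 7 and 3 consecutive tags, for which no chance test was run. The 7 tags around STER_1841 moved as a block, with a median log2 ratio of -0.76 on array 1, -0.56 on array 2 and -1.47 on array 3. The block was delimited as consecutive tags below -0.4 on every array. Its low values in the main setting and the break at its ends are therefore partly built in. The tags directly before and after the block had log2 ratios of -0.14 and -0.04 in the clone mean, but on array 1 the 2 tags before it read -0.55 and -0.62, about as low as the block. The block was lower on all arrays under the main setting and 4 other scalings, and 6 or 7 of its 7 tags were called lower in each. With the 3 arrays taken as independent, and without array 3, 0 of the 7 were called. The log2 ratios of the block were -1.09 to -0.81 and -0.75 to -0.59 in these settings. Its size, unlike its direction, differed between arrays 1 and 3, which held the same RNA.

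One hypothesis is that STER_0918 may be the disrupted locus itself. It had the lowest ratio of the 1921 loci on array 1, and the 3 tags after it rose with log2 ratios of 2.06, 2.21 and 2.24. The locus was singled out for its lowest clone mean, which rests on array 1, so that rank is no separate support. LexA-type repressors, to which HdiR belongs, carry a conserved motif around the catalytic serine of their self-cleaving domain. All 8410 probes were translated in 6 frames and searched for the motif G, then D, E or N, then S, M, any residue and P. Probes of 2 loci encoded it in a frame without a stop. One was the STER_0918 probe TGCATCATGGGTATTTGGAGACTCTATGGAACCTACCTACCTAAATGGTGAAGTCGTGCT, which encodes GDSMEP in the strand as printed on the array and read -4.32, -0.97 and -0.92 on the 3 arrays, with 1 of its 2 knockout spots well above background on array 1. The other locus carried it only on the strand opposite to the printed probe and had a log2 ratio of 0.26. The motif also occurs in other peptidases and the probes cover only part of each gene, so the identity of the locus stays open. The knockout signal of 619 and 646 on arrays 2 and 3, where negative controls read about 62.2 and 63.9, is not what a removed gene would give, unless other cDNA bound these probes there.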
